A study of Mus musculus with 6 samples.

How the data were processed

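Total RNA from purified splenic CD4+ T cells was sequenced in 3 libraries of C57BL/6J mice (CONT) and 3 libraries of db/db mice (DM). RNA was extracted with Trizol and libraries followed Illumina protocols, per the labels' protocols. The genome build GRCm38 and the tools cutadapt 1.9 and FastQC are named in the submitters' processing notes. The aligner and the program that quantified genes are not given in the sources used here, nor is the treatment of reads that match several genes or of strand.

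The authors deposited 1 table of the whole series with 28945 genes, gene and transcript identifiers, gene type, GO terms and a value per library. The authors deposited expression as FPKM, fragments scaled to transcript length and library depth by a program not given in the sources used here. The header calls the values counts, but they are in FPKM: multiplied by transcript length, part of the low values of single-transcript genes falls on steps whose size differs between libraries. The step size came from 15403 such genes, as the size with the most values within 0.02 of a whole step; 14.3% to 16% of low values fell there, against 3.93% to 4.44% for the median of the sizes tried, so most low values were on no step. The steps gave relative depths between 0.802 and 1.12; absolute depth is unknown, so no counting interval is given. The authors' deposited table also held a p-value and a q-value per gene, a ratio (fold change) of group means, its log2, and a flag for genes past both a p and a fold threshold. The authors' p-values and q-values came from a test that is not given in the sources used here; they are quoted only as the authors' own values, beside results computed here. No per-sample column was left unused.

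The design written before the data were examined assumed counts and named a count test as the main test, with limma on log2 values as the test for normalized values. As the values are FPKM, limma was used and the count tests DESeq2 and edgeR were not used. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trended prior variance, robust to outlying genes, and no covariate. Genes needed a mean of at least 1 FPKM in CONT or DM, which left 13106 genes and put 15839 below the level tested. Genes with a Benjamini-Hochberg adjusted p below 0.05 are called changed. A fold change is on the log2(FPKM + 1) scale, which understates the change of low genes. Means and SDs are of FPKM over 3 libraries.

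The procedure was tested on simulated data, in 5 runs on 13106 genes with 200 changed each, for DM against CONT. Calls were made for 15.2% of genes changed by 1 on the log2 scale, 67.8% of those changed by 2 and 0.0356% of unchanged genes. The noise was drawn independently for each gene and library. Genes of these libraries vary together, with an estimated correlation of 0.95 within the ribosomal protein list, so these rates need not hold for them.

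In all, 44 gene lists were fixed before the data were examined, covering T cell subsets and signalling, calcium entry, metabolism, vitamin D, bone-active factors, stress, strain-variable genes and markers of other blood cells. Lists with at least 5 tested genes, 42 in number, were tested with camera in limma at an inter-gene correlation of 0.01, and again with an estimated correlation and with fry. GO terms from the deposited table with 15 to 250 tested genes were tested in the same way; this was chosen after the data were seen. Lists also give the number of genes that passed when adjusted over the list alone.

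Genes named in the text follow a rule fixed in advance. It took the 10 largest and 10 smallest fold changes among changed genes whose groups did not overlap and whose mean was at least 1 FPKM, leaving out predicted genes, pseudogenes and receptor segments. It added 17 fixed genes of regulatory and helper T cells, calcium entry, vitamin D, leptin and bone, up to 4 genes per list by smallest adjusted p, and up to 4 per marker list by highest level. Some genes that the rule takes are not reported here. Genes outside the rule are named where a list's calls are counted, where a count of calls is 5 or fewer, or as marked in the text.

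Identifiers were matched to GENCODE M21, an annotation of GRCm38, for 28864 of 28945 genes (99.7%), and coordinates are 1-based from that annotation. Libraries of CONT and DM share replicate numbers, and the labels do not say that these pair the samples. Alternatives fixed in advance were median-of-ratios, upper quartile and total scaling, other filters and pseudocounts, a replicate block, other thresholds, leaving out abundant gene classes, an other-cell marker score as a covariate and leaving out each library. Quantile normalization, leaving out pseudogenes and receptor segments, and library quality weights were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.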

Results

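RNA was sequenced from CD4+ T cells purified from mouse spleen in 2 groups of 3 libraries. The CONT group came from C57BL/6J mice and the DM group from db/db mice, which carry a mutated leptin receptor and become obese and diabetic. The series title names eldecalcitol, an active vitamin D analogue, together with regulatory T cell differentiation and store-operated calcium entry, the influx of calcium through Orai channels that follows emptying of the endoplasmic reticulum store. No eldecalcitol sample was among the 6 libraries, so the comparison made here was DM against CONT, which asks how splenic CD4+ T cell RNA differed between diabetic and control mice. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these libraries, which may be technical.

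Expression was given as FPKM for 28945 genes. The FPKM of all genes summed to 248070, 327172 and 369531 in CONT replicates 1, 2 and 3 and to 410282, 398156 and 385070 in DM replicates 1, 2 and 3. Relative depth, read from the size of the smallest steps in FPKM times length, was 0.802, 1.12 and 0.986 in CONT and 0.995, 1 and 1.07 in DM. Read totals are not given in the sources used here, so counting error could not be computed per value. CONT replicate 1 stood apart from the other libraries: its mean correlation with its own group was 0.878 on log2(FPKM + 1), against 0.915 to 0.949 in the other libraries. Ribosomal protein genes took 6.88% of its FPKM, against 12.6% to 17.9% in the others. Immunoglobulin genes took 0.564%, 1.85% and 0.853% of FPKM in the CONT libraries and 5.08%, 3.39% and 7.08% in the DM libraries. Cd4 itself was at 220, 161 and 149 FPKM in CONT and at 82.4, 134 and 93.2 FPKM in DM.

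Leaving out receptor segments, pseudogenes and predicted genes, the largest increases in DM were in the MHC class II gene H2-Ea and the protease genes Mcpt2 and Mcpt8. H2-Ea, the alpha chain of the class II molecule I-E, was listed at 0 in CONT replicates 1 and 2 and at 0.244 ± 0.422 FPKM (SD, n = 3) over CONT, against 109 ± 140 FPKM (SD, n = 3) in DM. H2-Ea was at 18.2, 38.5 and 269 FPKM in DM replicates 1, 2 and 3. The class II gene H2-Ab1 was likewise highest in DM replicate 3 (109 FPKM, against 16 and 19). C57BL/6 mice do not transcribe H2-Ea because of a promoter deletion, so a strain difference may account for its rise. The mast cell protease Mcpt2 averaged 0.148 ± 0.257 FPKM (SD, n = 3) in CONT and 48.8 ± 28.3 FPKM (SD, n = 3) in DM, and the basophil protease Mcpt8 rose from 1.20 ± 0.641 to 105 ± 90.1 FPKM (SD, n = 3). Among the same genes the largest decreases were in Rpl21, a protein of the large ribosomal subunit, from 69.7 ± 53.6 to 3.02 ± 0.212 FPKM (SD, n = 3), and in Rab6b, a Golgi GTPase, from 8.50 ± 3.26 to 1.19 ± 0.422 FPKM (SD, n = 3). Apobec3, a cytidine deaminase that restricts retroviruses, fell from 19.4 ± 4.82 to 4.36 ± 0.481 FPKM (SD, n = 3).

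Of 13106 genes tested with limma, 199 changed at a Benjamini-Hochberg adjusted p below 0.05, of which 166 were higher and 33 lower in DM. At an unadjusted p below 0.05 there were 2099 of the 13106 genes, the share against which such counts in gene lists are to be read. In all 199 the DM libraries lay entirely above or entirely below the CONT libraries; over all genes tested 27.1% were separated in that way, where chance gives 10%. By class, the higher genes were 48 immunoglobulin segments, 39 pseudogenes, 3 predicted genes and 76 other genes. The lower genes were 6 T cell receptor segments, 4 pseudogenes, 9 predicted genes and 14 other genes.

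Among the 10 named genes with the largest increases, H2-Ea (chromosome 17, 34341959 to 34344645 on GRCm38) had a log2 fold change of 5.62 ± 0.88 (SE), with a limma adjusted p of 0.0338 (Benjamini-Hochberg). Mcpt2 (chromosome 14, 56042041 to 56044642) had 5.31 ± 0.39 (SE; limma adjusted p = 0.00292) and Mcpt8 (chromosome 14, 56082166 to 56085273) had 5.29 ± 0.58 (SE; limma adjusted p = 0.0111). The macrophage lysozyme Lyz2 rose by 4.11 ± 0.58 on the log2 scale and the basophil protease Prss34 by 3.92 ± 0.58. The log2 fold changes of the chitinase-like Chil3, the signalling adaptor Tyrobp, the IgG1 heavy chain gene Ighg1, the chemokine Ccl6 and the haemoglobin-binding Hp were 3.82, 3.74, 3.71, 3.48 and 3.18. The adjusted p of these 7 genes ran from 0.0151 to 0.0459 (limma, Benjamini-Hochberg).

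Among the 10 named genes with the largest decreases, Rpl21 (chromosome 5, 146832890 to 146837032) had a log2 fold change of -3.78 ± 0.59 (SE; limma adjusted p = 0.0334, Benjamini-Hochberg). Rpl21 has pseudogene copies that can share its reads, so its level is uncertain. Rab6b (chromosome 9, 103111787 to 103185276) had -2.08 ± 0.28, Insl6, an insulin-like peptide gene, had -2.02 ± 0.29, and Apobec3 (chromosome 15, 79891659 to 79915906) had -1.91 ± 0.22. The arginine deiminase Padi2 fell by 1.71 and the BMP9 receptor Acvrl1 by 1.70 on the same scale. Slc28a2b, Nat8f4, the tropomyosin Tpm3 and Rsl24d1 had log2 fold changes of -1.51, -1.46, -1.39 and -1.31. The adjusted p of the 9 genes after Rpl21 ran from 0.0114 to 0.0466 (limma, Benjamini-Hochberg).

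**Figure D1:**
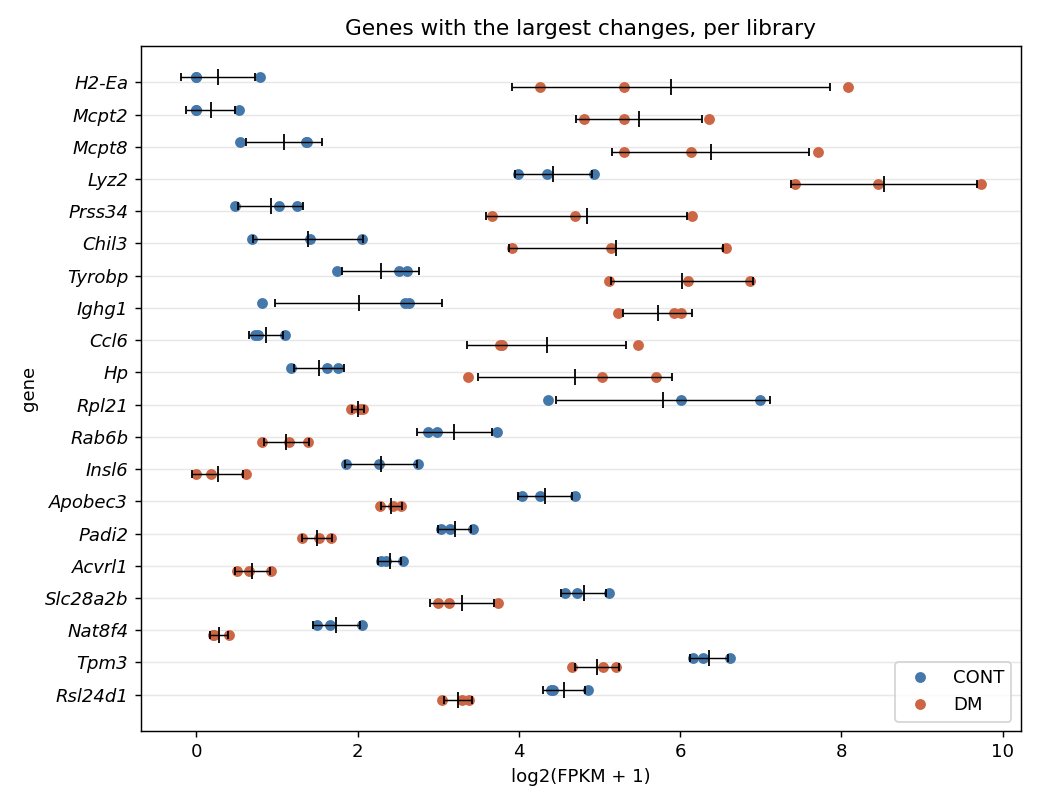
Expression of the 20 named genes with the largest changes, as log2(FPKM + 1) on the horizontal axis. Each point is a library (blue CONT, orange DM), the vertical tick is the group mean and the bar is 1 SD either side (n = 3). In each gene the DM points lie wholly on one side of the CONT points; H2-Ea runs from 0 to 0.73 FPKM in CONT and from 18.2 to 269 FPKM in DM.

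The number of calls varied with the libraries. It was 174, 192 and 87 without CONT replicates 1, 2 and 3 and 24, 133 and 67 without DM replicates 1, 2 and 3; each of these fits also has fewer samples, so a lost call need not mean a smaller fold. Among the 20 named genes only Mcpt2 and Mcpt8 passed with each of the 6 libraries left out in turn. With the level of other-cell markers as a covariate 4 genes passed, and with no filter on low values 28.

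Of the marker lists, 7 of other blood cell types were higher in DM and that of CD4 T cells lower with camera at a preset correlation but not at an estimated one (adjusted p 0.554 to 0.699, camera in limma, Benjamini-Hochberg), with few single genes called. The basophil and mast cell list had a median log2 fold change of 2.54 over 7 genes, and 4 of them rose: Mcpt8, Prss34, the mast cell carboxypeptidase Cpa3 (2.28 ± 1.24 to 22.5 ± 10.2 FPKM; SD, n = 3) and the IgE receptor chain Fcer1a. The plasma cell list had a median of 2.71 over 13 genes, with 2 higher, Ighg1 and the BCMA receptor gene Tnfrsf17. Medians were 2.32 over 16 neutrophil genes with none past the test, 1.86 over 15 erythroid genes with none, 1.80 over 19 macrophage and monocyte genes with 2 (Lyz2 and the Fc receptor Fcgr3), 1.46 over 8 dendritic cell genes with 1 (Cd209a) and 1.36 over 19 B cell genes with none. At an unadjusted p below 0.05 limma gave 8 neutrophil, 6 erythroid, 3 B cell and 6 CD4 T cell identity genes. Over all genes tested it gave 2099 of 13106, and the B cell count was near that share. The CD4 T cell identity list had a median of -0.52 over 17 genes, none of which passed alone and 2 of which were above 0. Cd3e, a chain of the T cell receptor complex, averaged 94.8 ± 35.6 FPKM (SD, n = 3) in CONT and 44.6 ± 10.6 FPKM (SD, n = 3) in DM. The chains Cd3d (109 ± 46.3 and 102 ± 20.7 FPKM) and Cd3g (159 ± 71.6 and 172 ± 37.6 FPKM) had log2 fold changes of -0.03 and 0.20 (SD, n = 3).

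With limma's camera test at a preset correlation of 0.01, the Benjamini-Hochberg adjusted p was 4.28e-10 for macrophages and monocytes, 9.19e-10 for plasma cells, 4.5e-07 for basophils and mast cells, 3.8e-06 for neutrophils and for dendritic cells, 1.96e-04 for erythroid cells, 5.8e-04 for B cells and 4.91e-04 for CD4 T cell identity. Adjusted over the list alone, 18 of the 19 macrophage and monocyte genes, 13 of the 13 plasma cell genes, 7 of the 8 dendritic cell genes, 6 of the 7 basophil and mast cell genes, 5 neutrophil genes and 3 B cell genes were higher. The B cell markers were carried by DM replicate 3: their mean log2(FPKM + 1) was 5.61 there, against 2.48 and 2.36 in DM replicates 1 and 2 and 1.80 to 2.46 in CONT. Without that library the B cell median was 0.52 and its adjusted p 0.108 (camera in limma, Benjamini-Hochberg). The lists of natural killer cells (median 0.20, 6 of 9 genes above 0, with 1 higher, Tyrobp), platelets and megakaryocytes (0.69) and gamma delta and innate-like T cells (0.46) had adjusted p of 0.241, 0.0903 and 0.0876 (camera in limma, Benjamini-Hochberg). Without DM replicate 1 the natural killer median was 0.41 and passed, with an adjusted p of 0.039 (camera in limma, Benjamini-Hochberg); with total scaling it was -0.04.

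The regulatory T cell genes, which the series title points to, were higher as a list with camera at a preset correlation (limma adjusted p = 0.00611, Benjamini-Hochberg) but not at an estimated one (0.699), with 1 of 29 genes called; Foxp3 itself did not pass the test. Foxp3, the transcription factor that defines these cells, averaged 18.7 ± 6.49 FPKM (SD, n = 3) in CONT and 14.4 ± 3.44 FPKM (SD, n = 3) in DM, a difference within the spread between libraries (log2 fold change -0.34 ± 0.29 SE; limma adjusted p = 0.501, Benjamini-Hochberg). The IL-2 receptor chain Il2ra was at 13.3 ± 5.40 and 10.9 ± 1.05 FPKM (SD, n = 3). The checkpoint receptor Ctla4 was at 27.0 ± 3.45 FPKM in CONT and 51.8 ± 1.88 FPKM in DM (SD, n = 3), with a log2 fold change of 0.92 ± 0.20 (SE) that missed the threshold over all genes (limma adjusted p = 0.0839, Benjamini-Hochberg). The inhibitory receptor Klrg1, also a mark of effector T cells, rose from 3.08 ± 0.463 to 10.6 ± 1.86 FPKM (SD, n = 3; log2 fold change 1.51 ± 0.20 SE; limma adjusted p = 0.0171, Benjamini-Hochberg).

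Over the 29 regulatory T cell genes tested, 1 rose (Klrg1), none fell and 28 did not pass; adjusted over the list alone, Klrg1 and Ctla4 passed. The list's median log2 fold change was 0.33 and 22 of its genes were above 0, Foxp3 (-0.34) and Il2ra (-0.20) not among them. Without CONT replicate 2 the median was 0.22 and the adjusted p 0.106 (camera in limma, Benjamini-Hochberg). With total scaling, under which the median of all genes was -0.32, the list's median was 0, and its comparison with other genes still passed (camera adjusted p = 0.02, limma, Benjamini-Hochberg). The other-cell marker score was higher in each DM library (3.58, 2.92 and 5.25) than in any CONT library (1.91, 2.37 and 2.06), so the list's rise need not be of T cells.

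Genes of store-operated calcium entry were lower in DM as a list at a preset correlation (adjusted p = 0.0346, camera in limma, Benjamini-Hochberg) but not at an estimated one (0.699), with no member past the test alone. The calcium sensor Stim1 averaged 9.75 ± 3.48 FPKM (SD, n = 3) in CONT and 5.81 ± 1.12 FPKM (SD, n = 3) in DM (log2 fold change -0.62 ± 0.27 SE; limma adjusted p = 0.312, Benjamini-Hochberg), and Stim2 was at 11.6 ± 2.11 and 9.07 ± 1.28 FPKM (SD, n = 3). The pore subunit Orai1 was at 6.81 ± 0.727 and 5.42 ± 0.515 FPKM, Orai2 at 26.6 ± 7.49 and 17.8 ± 5.69 FPKM, and Orai3 at 4.74 ± 0.336 and 5.71 ± 1.22 FPKM (SD, n = 3 each). Over 17 genes the median log2 fold change was -0.32, with 3 genes above 0, and 0 genes passed over all genes, adjusted over the list alone or at an unadjusted p below 0.05 (limma). Without CONT replicate 1 the median was -0.12 and the adjusted p 0.198 (camera in limma, Benjamini-Hochberg). CD4 T cell identity genes were lower in the same libraries, with a median of -0.52, while markers of other cells were higher, so the change need not lie within T cells.

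**Figure D2:**
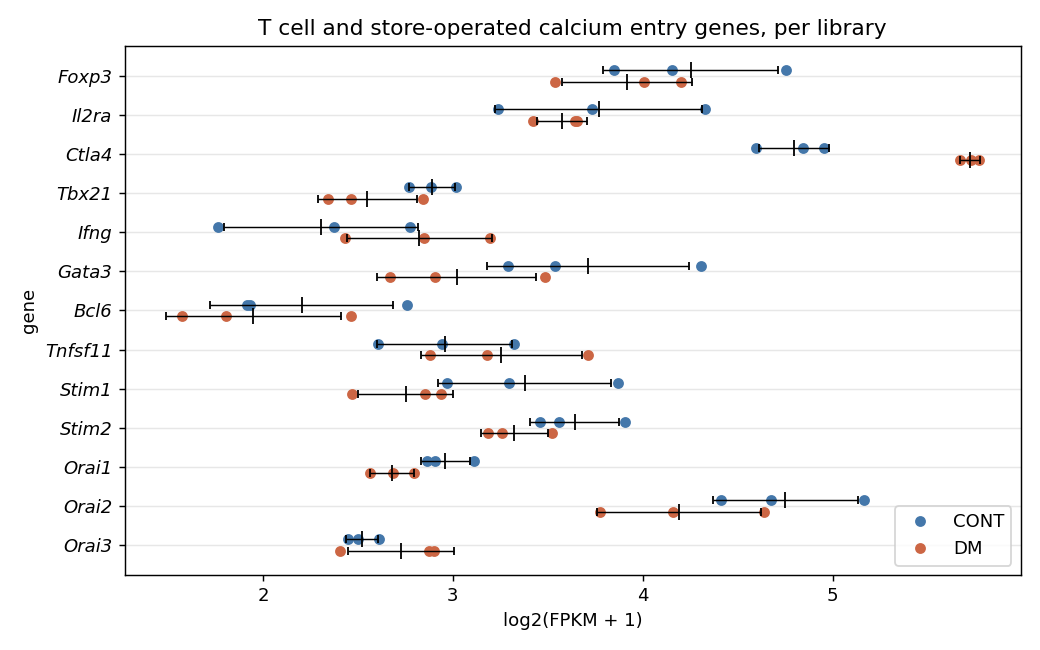
Expression of 13 T cell and calcium entry genes fixed in advance, as log2(FPKM + 1) on the horizontal axis. Each point is a library (blue CONT, orange DM), the vertical tick is the group mean and the bar is 1 SD either side (n = 3). None of the 13 passed the test over all genes; Ctla4 came nearest, at an adjusted p of 0.0839 (limma, Benjamini-Hochberg).

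T cell receptor signalling genes were lower as a list at a preset correlation (adjusted p = 7.64e-07, camera in limma, Benjamini-Hochberg) but not at an estimated one (0.692), with a median of -0.46 over 29 genes and 2 genes above 0. The surface receptor Cd5 was at 56.3 ± 9.86 and 33.2 ± 5.51 FPKM (SD, n = 3) in CONT and DM, and the phospholipase Plcg1 at 38.7 ± 11.1 and 21.8 ± 3.91 FPKM (SD, n = 3), with no member past the test and 10 at an unadjusted p below 0.05 (limma). The calcineurin and NFAT list, which acts downstream of calcium, had a median of -0.49 over 19 genes and did not pass (camera adjusted p = 0.0743, limma, Benjamini-Hochberg). CD4 T cell identity genes and Cd4 itself were lower in the same libraries, as given above.

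The effector and memory T cell list was higher and the naive T cell list lower at a preset correlation (adjusted p = 3.49e-07 and 7.49e-04, camera in limma, Benjamini-Hochberg) but not at an estimated one (0.554 and 0.699), with calls in the former only. Of 23 effector and memory genes 6 rose: S100a4 (27.2 ± 10.2 to 199 ± 60 FPKM; SD, n = 3), S100a6 (6.56 ± 1.68 to 46.2 ± 12.6 FPKM), Anxa1 (2.33 ± 0.326 to 26.9 ± 11.4 FPKM), Lgals3 (2.56 ± 0.465 to 26.4 ± 11.8 FPKM), Anxa2 and the chemokine receptor Ccr2. These calcium-binding, annexin and lectin genes are also expressed by macrophages, whose markers were higher in DM. The list's median was 0.82, and 9 genes were higher when adjusted over the list alone. Of the 18 naive genes none passed and 8 had an unadjusted p below 0.05 (limma); the homing receptor Ccr7 was at 115 ± 12.2 and 64.1 ± 18.1 FPKM (SD, n = 3) and the cytokine receptor Il7r at 150 ± 38.6 and 74.1 ± 19.4 FPKM (SD, n = 3) in CONT and DM. The naive list's median was -0.84, in libraries where CD4 T cell identity genes (median -0.52) and Cd4 itself were also lower.

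Among helper subsets, the T helper 17 list was higher at a preset correlation (adjusted p = 1.96e-04, camera in limma, Benjamini-Hochberg) but not at an estimated one (0.554), with 2 of 12 genes called, a median of 0.60 and all 12 above 0. Tmem176a and Tmem176b passed, with log2 fold changes of 1.28 ± 0.21 and 1.45 ± 0.22 (SE). Both are also expressed by dendritic cells and macrophages, whose marker lists were higher in DM, so the rise need not be of T cells. The T helper 1, T helper 2 and T follicular helper lists had medians of 0.25, -0.36 and 0.02 and did not pass (camera adjusted p = 0.26, 0.743 and 0.997, limma, Benjamini-Hochberg). In the T helper 1 list the protease gene Gzmb rose from 5.03 ± 1.83 to 20.1 ± 5.40 FPKM (SD, n = 3), while Tbx21 was at 6.43 ± 0.632 and 4.92 ± 1.11 FPKM and Ifng at 4.14 ± 1.73 and 6.25 ± 1.88 FPKM. Without DM replicate 1 the T helper 1 list passed, with a median of 0.39 and an adjusted p of 0.0478 (camera in limma, Benjamini-Hochberg). Gata3 was at 12.7 ± 5.32 and 7.35 ± 2.53 FPKM and Bcl6 at 3.80 ± 1.72 and 3 ± 1.34 FPKM (SD, n = 3), both within the spread between libraries. With total scaling the T helper 1 and T follicular helper medians were -0.03 and -0.31.

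Vitamin D, bone and leptin genes gave no calls over all genes. Vdr, the vitamin D receptor, was at 0.395 ± 0.175 FPKM (SD, n = 3) in CONT and 0.498 ± 0.0736 FPKM in DM, below the level tested, as were Lepr, the leptin receptor (0.0163 ± 0.0204 and 0.0487 ± 0.027 FPKM), and the cytokine Il17a (0.0232 ± 0.0401 and 0.501 ± 0.741 FPKM). Values of Lepr this low say nothing on the mutation of the db/db mice. Tnfsf11, which encodes the osteoclast factor RANKL, was at 6.92 ± 1.96 and 8.83 ± 2.94 FPKM (SD, n = 3; limma adjusted p = 0.534, Benjamini-Hochberg). The vitamin D list had a median of -0.35 over 10 genes and the bone-active factor list 0.30 over 9, and neither passed (camera adjusted p = 0.57 and 0.413, limma, Benjamini-Hochberg). Adjusted over the vitamin D list alone 1 gene was higher, the hydroxylase Cyp27a1, from 0.276 ± 0.0421 to 3.84 ± 2.77 FPKM (SD, n = 3, limma adjusted p = 0.0185 over the list and 0.0772 over all genes, Benjamini-Hochberg). Cyp27a1 was at 2.4, 2.08 and 7.03 FPKM in DM replicates 1, 2 and 3. The mean of the macrophage markers was also highest in DM replicate 3 (4.01, against 2.72 and 2.73), so the rise need not be of T cells. Insulin and leptin signalling fell as a list, with a median of -0.30 over 24 genes and an adjusted p of 0.0219 (camera in limma, Benjamini-Hochberg); the adjusted p was 0.699 with an estimated correlation. Without CONT replicate 1 its median was -0.06 and its adjusted p 0.182 (camera in limma, Benjamini-Hochberg), and no member passed alone.

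Cell cycle, oxidative phosphorylation, antioxidant and ribosomal protein genes were higher as lists at a preset correlation but not at an estimated one (adjusted p 0.699 to 0.711, camera in limma, Benjamini-Hochberg), with no call other than Rpl21, which was lower. Over 31 cell cycle genes all were above 0, with a median of 1.14 and 14 genes at an unadjusted p below 0.05 (limma): the proliferation marker Mki67 was at 24.7 ± 10.2 FPKM (SD, n = 3) in CONT and 72.0 ± 46.0 FPKM in DM, and Birc5 at 3.87 ± 2.01 and 13.5 ± 8.15 FPKM. In DM replicate 2 Mki67 was at 32.8 FPKM, within the CONT range of 15.7 to 35.8 FPKM. Mki67 was highest in DM replicates 1 and 3 (123 and 60.5 FPKM), where the mean of the erythroid markers was also highest (6.26 and 6.53 on log2(FPKM + 1), against 2.40 to 4.85 elsewhere), so the rise need not be of T cells. Of 51 oxidative phosphorylation genes 49 were above 0, with a median of 0.63 that was 0.27 without CONT replicate 1. The antioxidant list had a median of 0.57 over 21 genes; Hmox1, also expressed by macrophages, was at 5.93, 7.45 and 38.5 FPKM in DM replicates 1, 2 and 3, and the mean of the macrophage markers was highest in DM replicate 3 as well (4.01, against 2.72 and 2.73 in the other DM libraries). The camera adjusted p was 2.13e-08, 4.5e-07 and 9.02e-04 for these 3 lists (limma, Benjamini-Hochberg). The ribosomal protein list had a median of 0.71 over 76 genes, with Rpl21 as its only call, and an adjusted p of 1.96e-04 (camera in limma, Benjamini-Hochberg). Without CONT replicate 1 its median was 0.12 and its adjusted p 0.824, and without DM replicate 2 they were 0.58 and 0.0546 (camera in limma, Benjamini-Hochberg). The unfolded protein response list rose, with a median of 0.35 over 19 genes and an adjusted p of 0.0318 (camera in limma, Benjamini-Hochberg); the adjusted p was 0.699 with an estimated correlation. It did not pass without CONT replicate 1, DM replicate 2 or DM replicate 3 (adjusted p 0.14, 0.0723 and 0.0604; camera in limma, Benjamini-Hochberg), and with total scaling its median was 0.00. Some genes of this list, such as Xbp1, are high in plasma cells, whose markers were higher in DM (median 2.71). Glycolysis, fatty acid oxidation, cholesterol synthesis and fatty acid synthesis did not pass, with medians of 0.13, 0.26, 0.11 and -0.20; total scaling turned the sign of the medians of the glycolysis, fatty acid oxidation and cholesterol synthesis lists.

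**Figure D3:**
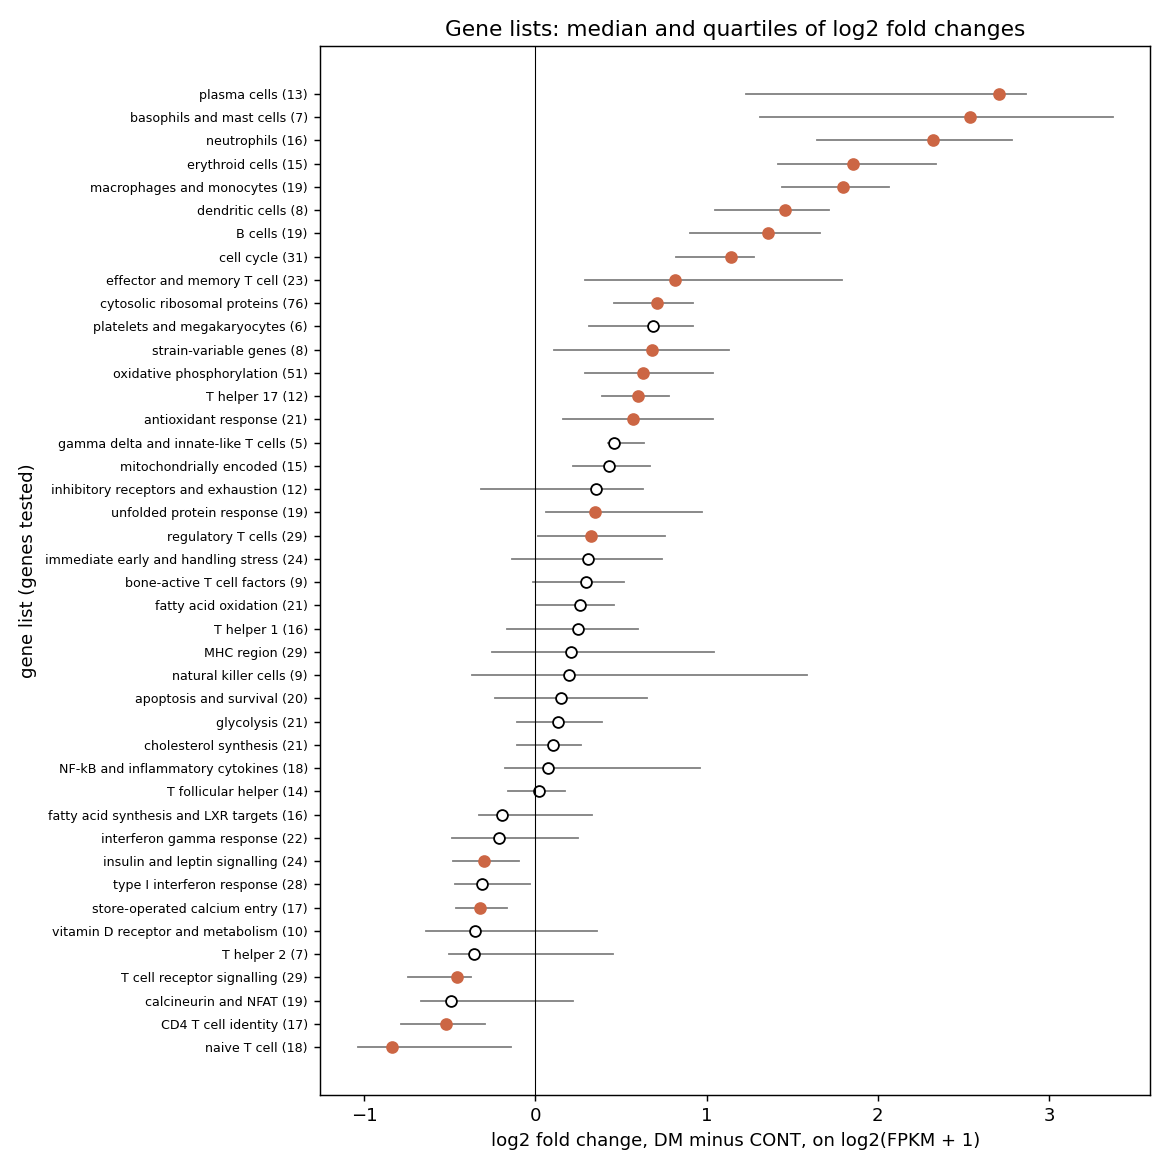
Median log2 fold change (DM minus CONT, on log2(FPKM + 1)) of the 42 gene lists with at least 5 tested genes, with the number of genes in brackets. Grey lines run between the quartiles, and filled points passed camera's test in limma at a preset correlation of 0.01. Plasma cells (2.71) and basophils and mast cells (2.54) lie highest and naive T cells (-0.84) lowest; with an estimated correlation 0 of the 42 lists passed.

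Across all 42 lists tested, 21 passed camera at the preset correlation, 16 higher and 5 lower in DM. With an estimated correlation 0 passed in limma's camera, 1 list having an unadjusted p below 0.05, and with fry, which tests whether genes of a list move 1 way on balance, 2 passed (T helper 17 and dendritic cells). With fry's test for change in either direction 14 passed. Among these were the T helper 1, inhibitory receptor, interferon gamma, NF-kB, bone-active factor, MHC region and natural killer lists, which did not pass camera. Of the 21 lists, 14 passed with each library left out in turn.

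Variable-region segments moved apart by receptor type. Of 194 immunoglobulin V segments 44 rose, none fell and 193 were above 0, with a median log2 fold change of 2.43. Of 138 T cell receptor V segments none rose and 5 fell (Trbv15, Trbv3, Trbv16, Trbv23 and Trbv12-1). Of the 138, 26 were above 0, with a median log2 fold change of -0.4. The J segment Traj23 fell as well, from 31.5, 23.4 and 29.6 FPKM in CONT to 1.44, 0.875 and 0.732 FPKM in DM. Trbv3 was at 91.4, 119 and 143 FPKM in CONT and at 12.1, 23.7 and 13.4 FPKM in DM. The segments were named after their values were seen. Near-identical segments share reads, which makes the level of any 1 segment uncertain.

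Genes that vary between inbred mouse strains were higher as a list at a preset correlation (adjusted p = 0.0263, camera in limma, Benjamini-Hochberg) but not at an estimated one (0.554). Of 8 tested genes known to differ between C57BL/6J and other strains 2 rose, H2-Ea and the glyoxalase Glo1 (4.94 ± 1.58 to 17.5 ± 2.83 FPKM; SD, n = 3), and adjusted over the list alone Nnt and Wdfy1 rose too. The list had a median of 0.68. Without CONT replicate 3 the adjusted p was 0.0696 (camera in limma, Benjamini-Hochberg). Of 29 MHC region genes tested 2 rose, H2-Ea and the class I gene H2-Q1 (4.20 ± 0.493 to 18.9 ± 3.96 FPKM, SD, n = 3). The list as a whole did not pass camera, with a median of 0.21 and 19 genes above 0 (camera adjusted p = 0.14, limma, Benjamini-Hochberg). It passed fry's test for change in either direction (fry adjusted p = 0.0027, limma, Benjamini-Hochberg), with 8 genes at an unadjusted p below 0.05 (limma). Without DM replicate 1 the MHC list's median was 0.31 and it passed (adjusted p = 0.00342, camera in limma, Benjamini-Hochberg); with total scaling the median was -0.14. The interferon-induced GTPase gene Gbp3, in the interferon gamma list, rose from 10.7 ± 1.24 to 57.9 ± 1.18 FPKM (SD, n = 3), with a log2 fold change of 2.34 ± 0.18 (SE; limma adjusted p = 0.00315, Benjamini-Hochberg). That list's median was -0.21 and it did not pass camera (adjusted p = 0.512, camera in limma, Benjamini-Hochberg). It passed fry's test for change in either direction (fry adjusted p = 0.00111, limma, Benjamini-Hochberg).

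The authors' deposited table flagged 3172 genes, 2272 up and 900 down, by an unadjusted p and a fold threshold. At a q below 0.05 the authors' deposited table held 1439 genes, 1198 of them higher in DM. Of the 199 genes called here with limma, 197 had a q below 0.05 in the authors' deposited table, and each of the 197 had the same direction. Both tests used the same libraries, so the like direction is no independent evidence. In reverse, 940 of the genes tested here had a q below 0.05 in the authors' deposited table, and 197 of these were called with limma.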

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

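Quantile normalization, leaving out pseudogenes and receptor segments, and library quality weights were chosen after seeing the data. The count of changed genes was 199 (166 higher, 33 lower) and stayed within 1.5 times of that under median-of-ratios, upper quartile, total and quantile scaling, both other pseudocounts, a filter of 1 FPKM in 3 libraries and a fold threshold. With no filter on low values 28 genes passed (23 higher, 5 lower), where more genes were tested. At an adjusted p below 0.01, 23 passed (22 higher, 1 lower; limma, Benjamini-Hochberg). Without immunoglobulin, haemoglobin, mitochondrial and ribosomal protein genes 116 passed (91 higher), and without pseudogenes and receptor segments 78 (63 higher, 15 lower), where fewer genes were tested. A mean of at least 5 FPKM left 19 lower genes. With the other-cell marker score as a covariate 4 passed (4 higher, 0 lower; limma), and 421 had an unadjusted p below 0.05, 116 of them lower; the score differs between the groups, and the fit has fewer residual degrees of freedom. With library quality weights 4528 passed (2015 higher, 2513 lower), but the weights did not converge and gave CONT replicate 2 a weight of 51.5, so this count is not usable. Leaving out 1 library gave 24 to 192 changed genes, 22 to 179 higher and 2 to 28 lower, with fewer samples in the fit.

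With the replicate block 204 genes passed (185 higher, 19 lower). Deviations of same-numbered libraries from their group means correlated at -0.382 to -0.203, and 0 CONT libraries correlated best with their own number. No pairing was seen in this way, but 3 libraries per group are too few to exclude it.

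The count of lists was 21; it was 0 with camera at an estimated correlation, 2 with fry, and 18 to 28 with a library left out. The median of the store-operated calcium entry list was -0.32 (adjusted p = 0.0346, camera in limma, Benjamini-Hochberg), short of the threshold under total scaling (-0.65, adjusted p = 0.0512), no filter (-0.27, 0.0913), a threshold of 0.01 (-0.32), without the abundant classes (-0.51, 0.0511), with the other-cell score (-0.33, 0.0578), with an estimated correlation (0.699) and with fry (0.362); it was -0.41 to -0.12 with a library left out, and its adjusted p ran from 0.0145 to 0.699 over 22 settings (camera and fry, Benjamini-Hochberg). The median of the regulatory T cells list was 0.33 and did not pass with an estimated correlation (0.699) or fry (0.304); it was 0.19 to 0.36 with a library left out, and its adjusted p ran from 3.13e-06 to 0.699 over 22 settings (camera and fry, Benjamini-Hochberg). With the other-cell score, which is built from their own markers, the median of the B cells list turned to -1.43 and that of the erythroid cells list to -0.38. The cause was not tested for the other changes.

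Over the 42 lists and all settings 822 outcomes were alike, 66 lost and 25 gained the threshold. Over the named genes 3713 were alike, 233 lost and 124 gained it, no called gene changed sign, and 33 outcomes of uncalled genes did. DESeq2, edgeR and voom were not run, as the values are not counts, and the depth behind a value is unknown.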

Other observations

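The tests on GO terms, on marker lists moving apart, on the other-cell score within the higher genes and on pseudogene families, also with a library left out, were chosen after the results were seen; the test on neighbouring genes was written before the data were examined, and its restriction to unlike names was added after.

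Of 1007 GO terms tested, 75 passed camera in limma, 62 higher and 13 lower in DM. The strongest was immunoglobulin receptor binding, with a median log2 fold change of 2.32 over 104 genes, 11 of them called higher, and a camera adjusted p of 3.24e-31 (limma, Benjamini-Hochberg); the adjusted p was 0.995 with an estimated correlation. Serine-type endopeptidase activity held 8 called genes among 43, and inflammatory response 6 among 93. The proteasome core complex had a median of 0.71 over 17 genes, the nucleosome 0.75 over 50 and peroxidase activity 1.19 over 16. Lower terms were protein kinase activity (median -0.22 over 206 genes), sequence-specific DNA binding (-0.23 over 182) and histone methyltransferase complex (-0.43 over 23). The adjusted p of these terms was 2.08e-02 or less at the preset correlation and 0.995 with an estimated correlation (camera in limma, Benjamini-Hochberg).

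Inflammatory, stress and mitochondrial lists did not pass camera as a whole, and 1 of their genes was called. In the NF-kB and inflammatory cytokine list the chemokine Ccl3 rose from 0.919 ± 0.538 to 10.7 ± 2.54 FPKM (SD, n = 3; log2 fold change 2.62 ± 0.27 SE; limma adjusted p = 0.0103, Benjamini-Hochberg), while Il1b was at 1.99 ± 1.25 and 13.1 ± 14.3 FPKM. Macrophage and neutrophil markers were also higher in DM (list medians 1.80 and 2.32), so the rise of Ccl3 need not be of T cells. The medians of the NF-kB list (0.07), the immediate early list (0.31), the inhibitory receptor list (0.36), the type I interferon list (-0.31), the mitochondrially encoded list (0.43) and the apoptosis list (0.15) did not pass. With a library left out 5 of these lists passed in some cases. Without DM replicate 1 the adjusted p was 0.00162, 0.00027, 0.0478 and 0.0104 for the NF-kB, immediate early, inhibitory receptor and type I interferon lists (camera in limma, Benjamini-Hochberg). The inhibitory receptor list also passed without CONT replicate 1 (0.0325), the type I interferon list without CONT replicate 2 (0.00178) and the mitochondrially encoded list without CONT replicate 3 (0.0168) or DM replicate 3 (0.0368; camera adjusted p, limma, Benjamini-Hochberg). In the strain-variable list Nnt was at 1.98 ± 0.215 and 3.50 ± 0.357 FPKM (SD, n = 3). CD8 T cell and stromal lists held 2 and 3 tested genes and were not tested as lists. The CD8 T cell genes stood out in DM replicate 3: Cd8a was at 12.7 FPKM there, against 0.131 to 0.967 FPKM in the other libraries. Cd8b1 was at 39 FPKM there, against 4.51 to 7.65 FPKM.

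Strain background is a candidate explanation for part of the 199 calls. C57BL/6 mice do not transcribe H2-Ea because of a promoter deletion, and db/db mice are kept on several inbred backgrounds; the labels do not name the background here. Changed genes were neighbours along chromosomes in 28 pairs against 0 to 7 in the central 95% of 10000 random draws. Such draws take no account of like genes lying side by side, as the 48 higher immunoglobulin segments do, so this count does not bear on strain. Without receptor segments and counting only pairs of unlike names there were 7 pairs against 0 to 4, with 8 in the highest draw. Among them were Apobec3 with a transcript beside it (both lower) and Mtmr9 with Xkr6 (both higher), although Cma1 with Mcpt2 and Aif1 with Lst1 are also genes of 1 cell type each. The MHC window of chromosome 17 (33000000 to 37000000) held 8 higher and 1 lower gene among 150 tested, 6% against 1.52% of all genes. Aif1 and Lst1 are among the 8, so cell type may supply part of this excess too. Strain and diabetes cannot be told apart in this design. Of the 10 splits of the 6 samples into 3 and 3, the real one called 199 genes and the highest other 1, and 10 splits cannot give a share under 0.1.

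Several marker lists of other cell types were higher in DM. A lower share of CD4 T cells would raise the markers of every other type alike. The basophil list rose by 2.07 ± 0.47 (SE) more than the platelet list, with values of -0.92, -0.23 and -0.23 in CONT and 2.18, 1.85 and 0.82 in DM. This cannot decide the question, as the platelet gene with the highest level, Itgb3, was lower in DM (16.6 and 8.47 FPKM), like T cell genes. Pf4 and Itga2b averaged 0.782 and 0.606 FPKM in CONT, where the log2(FPKM + 1) scale understates a change. RNA of B cells, macrophages, neutrophils and erythroid cells may still account for many of the higher calls. With their score as a covariate the median log2 fold change of the 166 higher genes went from 2.57 (median SE 0.32) to 2.01 (median SE 0.48), and 4 genes still passed; the fold was smaller, the error larger and the residual degrees of freedom fewer, and which of these ended the other calls was not tested. The score lies higher in every DM library, so the score and the group cannot be told apart. A real change of these cells in the DM spleen and a difference in the purity of the preparations both stay open and were not tested.

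Pseudogenes were 39 of the 166 higher genes. In 9 families with 16 higher pseudogenes, 1 parent was called lower (Rnps1), 1 higher (Glo1) and 7 did not pass. The parent Rpsa averaged 1360 FPKM in CONT and 661 in DM without passing (limma adjusted p = 0.355, Benjamini-Hochberg), while the summed FPKM of its 10 named copies went from 217 to 4550. A higher level of the parents spilling into their copies needs parents that rise about as much as the copies. The parents' measured FPKM had a median log2 fold change of -0.59 ± 0.41 (SE over the 9 families). This argues against such spilling for the families as a set only if the share of reads passing to copies was alike in both groups. A larger share in DM would itself lower the parents' FPKM, and the share was not measured. The copies, chosen for being called higher, rose by 2.02 to 4.53. Most families are of ribosomal protein genes and may vary together, which this SE does not count. For Glo1, which rose by 1.66, such spilling stays open in either case. Reads passing from parents to copies, as a strain variant could cause, stay open. The summed FPKM times length of parent and copies rose by a median of 0.82 ± 0.28 (SE over families). This lay within 1 SE of the median of ribosomal protein genes (0.71). The sums changed by -0.02 for Atp6v0c, 0.19 for Rnps1 and 2.04 for Glo1. Length was that of the longest annotated transcript, which can weight a parent above its copies. Summed without length, the median was 1.18, with 1.02 for Atp6v0c, 1.08 for Rnps1 and 3.15 for Glo1. Of the 9 sums with length 8 were above 0 and 5 did not overlap between the groups. But the families were chosen for a higher copy, which by itself raises the sums. Without CONT replicate 1 the median of the sums with length was 0.44 ± 0.24 (SE over families) and that of ribosomal protein genes 0.12, within 2 SE. The levels of these parents and copies are uncertain.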
